A study of Camponotus floridanus with 48 samples.

How the data were processed

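Whole-body polyA RNA of 48 female terminal-stage larvae was sequenced in pairs of reads with a directional kit, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.20, Trim Galore 0.6.7, Salmon, DESeq and DESeq2, with no role or order. The version of Salmon, its index, its strand setting and the genome build are not given in the sources used here. The deposited table of each larva holds estimated counts (expected counts) per transcript and effective transcript lengths, per the file headers, which are those of a salmon quantification. A deposited table of the whole series holds a normalized signal per transcript and larva. Compared with the estimated counts, its values are counts divided by a factor that varies between transcripts of 1 library. The authors' deposited normalized table was used only for an alternative. It has 26314 transcripts, a first line with the larval lengths that was left out, and 1 cell that is not a number, and 0 of its columns belong to other samples.

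Each of the 26315 transcripts in the files was matched to a gene through the RefSeq annotation of Cflo_v7.5. Of these, 25811 matched by versioned accession, 348 by gene symbol and 155 carried tRNA names, which gave 13878 genes. The remaining transcript names no gene. It took at most 0.00124% of a library and stayed out of library sizes and tests. No coordinates are printed, because no build is named with the files, and the annotation was used only for names, gene classes and the order of genes. No pair of libraries held identical values.

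Estimated counts were summed over the transcripts of each gene and rounded to whole numbers. Genes passing filterByExpr were scaled by TMM factors and tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16, with larval length in mm as the covariate and all 48 larvae in the fit. The slope is the log2 change per mm, its SE is the slope divided by the square root of F, and p-values were adjusted by Benjamini-Hochberg at 0.05. Curved relations were tested with the 2 extra terms of a natural spline of 3 degrees of freedom over a line. Isoform usage was tested on rounded transcript counts with diffSpliceDGE, for genes with at least 2 transcripts passing the filter. Classes of genes with at least 5 members were tested with camera on voom values in limma 3.58.1, with an estimated correlation. Co-expression is the mean absolute Pearson correlation among 1000 genes on log2 CPM with a prior count of 2. It was compared with 100 random splits. Principal components were computed on the same log2 values. Printed CPM values are counts per library size after scaling by the TMM factors. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

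The tests, the covariate, the alternatives and the rule for named genes were fixed before the data were examined. The rule names the 8 rising and 8 falling genes of smallest p with a mean of at least 5 CPM, up to 2 called members of each gene list, 13 further entries by name, and the 5 genes of smallest p for curves and for isoform usage. It also asked for a product name that is not "uncharacterized". That condition could not be applied, because the gene table used here pairs transcripts with symbols and not with products. For the same reason 0 of the 28 lists reached 5 genes, 1 list had a single match, and 0 of the 13 entries matched. The planned list test was therefore not run, and gene classes of the annotation were tested in its place.

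Alternatives fixed in advance were RLE and upper-quartile factors, no filter on low counts, DESeq2 1.42.0, limma-voom, single transcripts, an offset for transcript length, the authors' normalized table as log2(value + 1), and length as a log2 value or in groups. Covariates tried were the total count, the ant number and 2 surrogate variables from sva 3.50.0. Each larva was also left out in turn, as were the 2 longest with the 2 shortest. Added after the data were seen were fits without larvae No. 42 and No. 43, fits without the 15 libraries with a first-component score above 20 or with these as a covariate, each library's trend with transcript length as a covariate, and the gene classes.

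The scripts were tested on simulated counts with the real gene means, library sizes and dispersions. Apart from the changes put in, genes were drawn independently of each other. The simulated libraries therefore lack the variation that genes share in the real ones, and error rates and recovery in the real data may differ. Of 200 genes given a slope of 0.25 log2 per mm, 53% were recovered, with 83.5% at 0.5 and 96.5% at 1, among 10479 to 10484 genes. Calls on unchanged genes made up 4.50%, 6.18% and 3.98% of calls. For curves of 1 and 2 log2 units in height, 55% and 85.5% of 200 genes were recovered, with 5.17% and 7.57% of calls on unchanged genes. For isoform usage, 37% of 200 genes with a change of 0.5 log2 per mm and 72% at 1 were recovered, with 20.4% and 16.8% of calls on unchanged genes, above the nominal rate. A shift of 0.3 log2 per mm in all 444 long non-coding RNA genes was called in 20 of 20 simulated sets, and in 1 of 20 with no shift. A shared factor with an SD of 1 log2 unit, simulated in the larger larvae alone, raised the co-expression difference to 0.397 (permutation p = 0.0099). No smaller factor was simulated, so this does not show how small a difference could be found in the real larvae.

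Library totals ran from 6608775 to 63171625 reads, and counting error is largest in the 2 shallowest libraries. The spread between larvae beyond counting error was estimated by edgeR at a coefficient of variation of 44.2%. All larvae came from 1 colony, so p-values measure the spread between larvae of that colony. How the quantification divided reads between isoforms, near-identical gene copies and overlapping genes is not known here, and values of such genes and of minor transcripts are uncertain.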

Results

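Messenger RNA was sequenced from the whole bodies of 48 female larvae of the Florida carpenter ant, Camponotus floridanus, a species whose workers differ widely in body size. All larvae were at the terminal larval stage and came from 1 colony, and each was a separate animal with its own library. Their lengths ran from 4648.07 to 7598.06 µm, with a largest gap between neighbouring lengths of 193 µm and a mean of 6069 ± 903 µm (SD, n = 48), so the larvae form 1 group ordered by a measured length. For description, values are also given for the 16 shortest larvae (4648.07 to 5376.84 µm) and the 16 longest (6689.42 to 7598.06 µm). The libraries held 6608775 to 63171625 reads assigned to genes. Larvae No. 42 and No. 43, both among the 16 longest, had 8928672 and 6608775 reads, and every other library had at least 29813793. Genes are named by the symbols of the RefSeq annotation of assembly Cflo_v7.5, which for all but 4 of the 13878 genes is a locus number or a tRNA name. No product names were used here, so most genes are reported without a known function.

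The first principal component of expression held 44.0% of the variance between libraries and the second 10.03%. On the first component 15 libraries had scores from 27.9 to 121, while the other 33 had scores from -62.9 to 5.84. Of these 15 larvae, 2 were among the 16 shortest, 8 were of intermediate length and 5 were among the 16 longest. They included 12 of the 14 larvae from 5850.88 to 6892.55 µm. The labels name no batch. The 15 larvae were No. 3, 4, 6, 9, 15, 17, 29, 31, 32, 33, 36, 38, 49, 53 and 68, which is uneven along the numbering, and what the numbering stands for is not given in the sources used here. The trend of expression with transcript length, in log2 per doubling of length relative to the mean of all libraries, ran from -0.27 to -0.01 in the 15 and from -0.11 to 0.19 in the other 33. The sign of a component is arbitrary, and components after the first were oriented to rise with length over all larvae. The second component rose with length in all 48 larvae (Pearson r = 0.640, Spearman rho = 0.652, permutation p = 1e-05 for each, the smallest the permutations can give, adjusted p = 8e-05 over 8 relations). It also rose within the 33 larvae (r = 0.684, rho = 0.707, permutation p = 5e-05 and 2e-05, adjusted p = 0.0002 and 8e-05) and within the 15 (r = 0.720, rho = 0.775, permutation p = 0.00168 and 0.00102, adjusted p = 0.00448 and 0.00272). Leaving out the 2 larvae farthest from the median length gave r = 0.616, 0.654 and 0.760 in the same order. The first component rose with length within the 33 larvae (r = 0.480, rho = 0.400, permutation p = 0.00495 and 0.0225, adjusted p = 0.0099 and 0.045, r = 0.524 without the 2 farthest). Within the 15 it did not pass the test (r = 0.367, rho = 0.368, permutation p = 0.178 for each, adjusted p = 0.284 and 0.285, r = -0.0816 without the 2 farthest). The third component had no detectable relation with length (r = 0.0244, rho = 0.0231, permutation p = 0.870 and 0.876, adjusted p = 0.870 and 0.876, r = 0.0438 without the 2 farthest).

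**Figure D1:**
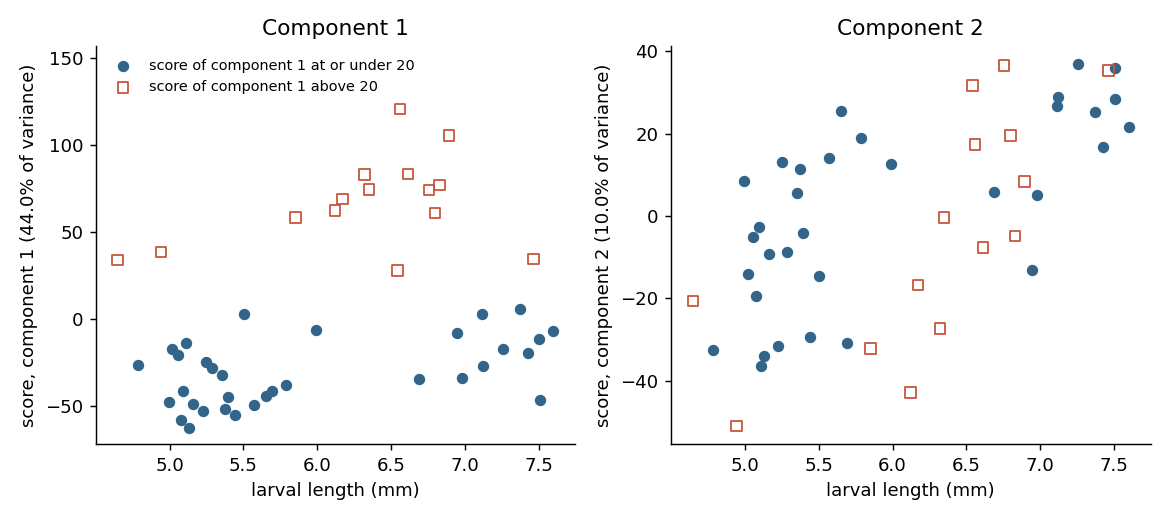
Scores of the 48 libraries on the first and second principal components of log2 CPM, against larval length in mm. Squares mark the 15 libraries with a first-component score above 20, 8 of them from larvae of intermediate length, and the second component rises with length in both sets of libraries.

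The most abundant transcripts differed in how they followed length. These 6 genes were chosen for their abundance after their values were seen. LOC105250772 had a mean of 45717 CPM. It fell with length (slope -0.19 ± 0.06 log2 per mm, SE, edgeR adjusted p = 0.0101), from 53940 ± 8981 CPM in the 16 shortest larvae to 38941 ± 12107 in the 16 longest (SD, n = 16 each). LOC105256665 rose (slope 0.61 ± 0.17, adjusted p = 0.00474) from 13264 ± 6416 to 29390 ± 17135 CPM, with 34392 ± 26207 in the 16 larvae of intermediate length and slopes of 0.40 to 0.72 over 14 alternative fits. In turn, LOC105255423 rose (slope 0.40 ± 0.09, adjusted p = 0.000532) from 17543 ± 4757 to 29271 ± 7309 CPM. LOC105258900, LOC105258901 and LOC105258932 stand next to each other in the gene table. Their joint level in TMM-scaled CPM, written as a percentage, averaged 8.78%, which is not the exact share of a library's reads. Their slopes with length were -0.20 ± 0.35, -0.21 ± 0.35 and -0.18 ± 0.35 and did not pass the test (adjusted p = 0.709, 0.695 and 0.742), and their sign differed between alternative fits, with slopes of LOC105258900 from -0.45 to 0.23. Their joint scaled level ranged from 0.00209% in larva No. 33 to 23.6% in larva No. 43. In the 15 libraries with high first-component scores this level lay between 0.00209% and 4.81%, and in the other 33 between 0.169% and 23.6%.

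**Figure D2:**
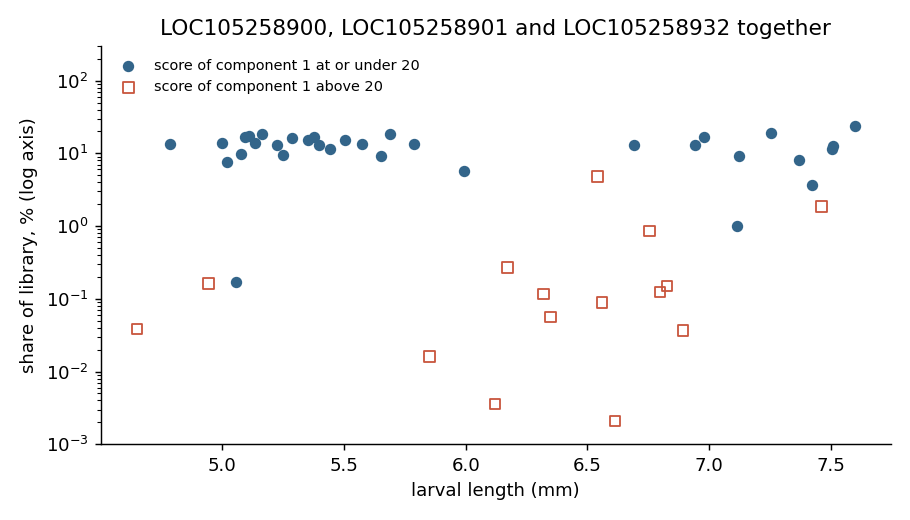
Joint level of LOC105258900, LOC105258901 and LOC105258932 in each of the 48 libraries, as TMM-scaled CPM written as a percentage (log axis), against larval length in mm. The axis labels this value a share of the library, but it is not the exact share of reads. Squares mark the 15 libraries with a first-component score above 20, in which the level is at most 4.81%. Larva No. 51 is the only other library under 1%, at 0.169%.

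The main comparison asked which genes change with larval length, the size that the labels give for each larva. The labels record neither adult size nor age within the stage, so slopes with length cannot be read as effects of worker size. Expression of 3234 of 10513 tested genes (30.8%) was associated with length, of which 1769 rose and 1465 fell (edgeR quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05, n = 48). Rising genes made up 54.7% of these calls. With upper-quartile scaling they made up 41.8% (1419 rising, 1976 falling), so the balance of directions depends on the scaling. Changes were modest for most genes, with a median slope of 0.32 log2 per mm among rising genes and -0.18 among falling genes. Slopes above 1 log2 per mm were found for 208 rising genes, and slopes under -1 for 8 falling genes. Without the 15 libraries with high first-component scores, 1755 genes rose and 1769 fell, and 2547 of the 3234 calls were kept in the same direction. The number with a slope above 1 dropped from 208 to 61. Of the 208 genes themselves, 130 were still called rising and 47 kept a slope above 1.

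**Figure D3:**
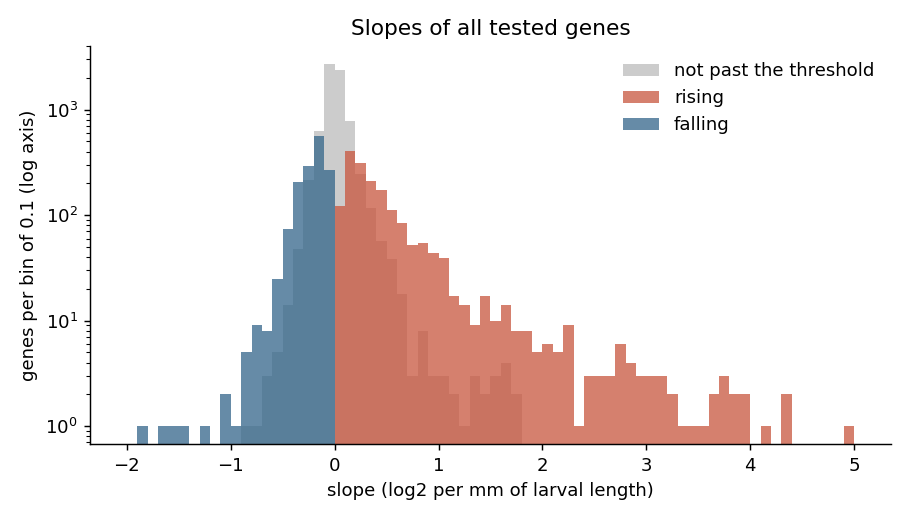
Slopes of the 10513 tested genes in log2 per mm of larval length, as the number of genes per bin of 0.1 on a log axis; the bars overlap. The 1769 rising genes reach further from 0 than the 1465 falling genes, with 208 slopes above 1 against 8 under -1.

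Among genes with at least 5 CPM on average, the 8 with the smallest p that rose with length were LOC105258509, LOC105249648, LOC105254163, LOC105249930, LOC105248781, LOC105251665, LOC105249932 and LOC112637522. Their adjusted p ran from 3.15e-10 to 2.16e-08. For each of them, all 16 of the longest larvae lay above the median of the 16 shortest. LOC105258509 rose from 9.39 ± 3.04 CPM in the 16 shortest larvae to 41.5 ± 17.2 in the 16 longest (SD, n = 16 each), a 4.42-fold difference, with a slope of 0.98 ± 0.09 log2 per mm. LOC105249932 was by far the most abundant of the 8, and rose 2.39-fold from 3802 ± 956 to 9087 ± 2075 CPM. The long non-coding RNA gene LOC105249930 rose from 4.83 ± 2.75 to 22.2 ± 7.58 CPM, which is 4.61-fold. LOC112637522 had the steepest slope of the 8 (1.20 ± 0.14), and rose 5.10-fold from 14.1 ± 1.89 to 71.8 ± 32.9 CPM. LOC105254163 rose least, 1.59-fold, from 36.3 ± 4.15 to 57.6 ± 12.6 CPM. All 8 passed the test in each of the 14 alternative fits that give a slope per mm for a gene. These fits use the larvae by which the genes were chosen, so they show dependence on the processing and give no independent support.

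The 8 falling genes with the smallest p, again among genes with at least 5 CPM on average, were LOC105257547, LOC105251399, LOC105249411, LOC105252472, LOC105248417, LOC105258095, LOC105248853 and LOC105254456. Their adjusted p ran from 7.21e-10 to 6.80e-09. All 16 of the longest larvae lay below the median of the 16 shortest for each. LOC105257547 fell from 20.3 ± 3.20 CPM in the 16 shortest larvae to 11.01 ± 2.85 in the 16 longest (SD, n = 16 each), so that the shortest had 1.85-fold more. LOC105248417 fell from 33.8 ± 3.13 to 18.3 ± 5.21 CPM, and LOC105249411 from 9.50 ± 1.45 to 5.27 ± 1.27 CPM. The smallest difference of the 8 was that of LOC105254456, with 1.39-fold more in the shortest larvae. These 8 genes also passed the test in each of the 14 alternative fits, which again use the larvae by which they were chosen.

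**Figure D4:**
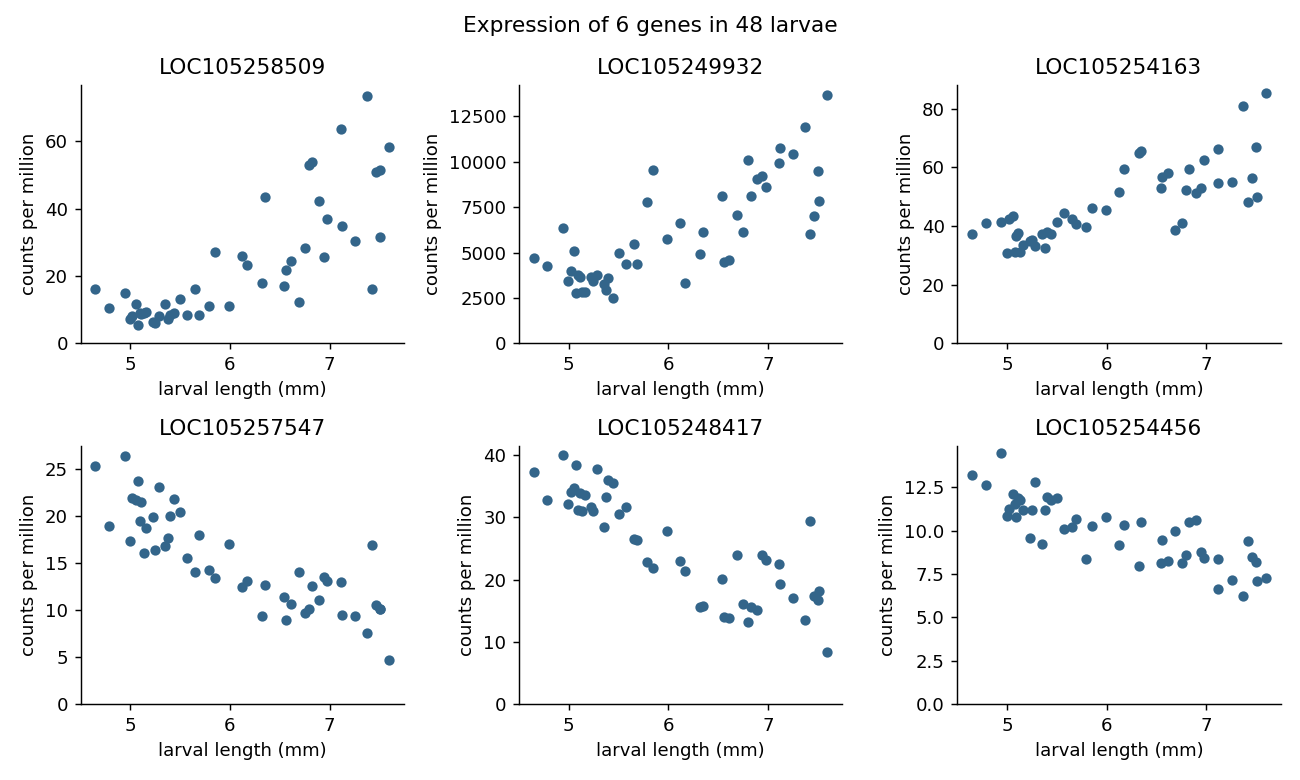
CPM of 3 rising genes (upper row) and 3 falling genes (lower row) in each of the 48 larvae, against larval length in mm. LOC105258509 is 4.42-fold higher on average in the 16 longest larvae than in the 16 shortest, and LOC105257547 is 1.85-fold higher in the 16 shortest.

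Of the 28 gene lists fixed for this comparison, only the list of muscle genes had a member that could be matched by name. That member was Titin, the giant elastic protein of muscle sarcomeres. Titin rose with length (slope 0.35 ± 0.09 log2 per mm, edgeR adjusted p = 0.00193), from 17.2 ± 5.69 CPM in the 16 shortest larvae to 27.9 ± 7.49 in the 16 longest (SD, n = 16 each). All 16 of the longest larvae lay above the median of the shortest. Its level in the 16 larvae of intermediate length was 29.4 ± 13.9 CPM. Adjusted over the list alone, 1 of 1 genes passed. As 1 gene of a list, it does not describe muscle genes as a group.

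In place of the lists, the annotation's gene classes were compared with length, a comparison chosen after the data were seen. Among long non-coding RNA genes, 75 of 444 (16.9%) rose and 26 (5.86%) fell. Among pseudogenes, 31 of 121 (25.6%) rose and 6 (4.96%) fell. Neither class passed a test of a shift as a whole against the other genes (camera, adjusted p = 0.748 for each with an estimated correlation). With a preset correlation of 0.01, camera gave p = 0.0294 for long non-coding RNA genes and 0.0193 for pseudogenes (adjusted p = 0.0735 for each). A shift of either class is therefore not excluded. Protein-coding genes numbered 9909, of which 1660 rose and 1432 fell. The 9 tested genes of the class misc_RNA, of which 3 rose and 1 fell, passed a test of a common direction (fry, adjusted p = 0.012) but not camera with an estimated correlation (adjusted p = 0.748). Over all alternatives its adjusted p ran from 0.012 to 0.747. Pseudogenes can share reads with the genes they derive from, so their values are uncertain.

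A second question was whether expression followed length along a straight line. A curve passed the test for 5735 of the 10513 genes (edgeR quasi-likelihood F test of a natural spline with 3 degrees of freedom against a line, adjusted p under 0.05). With a quadratic term in place of the spline, 170 genes passed. Of the 5735 genes, 2987 were higher in the 16 larvae of intermediate length than the average of the 16 shortest and the 16 longest, and 2748 were lower. The 5 genes with the smallest p were LOC105258560, LOC105248331, LOC105257682, LOC105251514 and LOC105251454, with adjusted p from 6.17e-08 to 2.67e-07. LOC105258560 was at 0.208 ± 0.114 CPM in the 16 shortest larvae, 10.3 ± 16.8 in the 16 of intermediate length and 2.36 ± 5.73 in the 16 longest (SD, n = 16 each). LOC105251454 followed the same order, with 6.66 ± 12.0, 103 ± 142 and 38.2 ± 87.3 CPM. In the larvae of intermediate length the SDs of both genes exceeded the means. Without the 15 libraries with high first-component scores, edgeR called 0 genes curved, with 230 of 10481 at an unadjusted p under 0.05. With those libraries as a covariate it also called 0, with 338 of 10513 at an unadjusted p under 0.05. Both counts are under the 5% of genes that would pass with no curve. As 12 of the 14 larvae from 5850.88 to 6892.55 µm are among the 15, both fits also remove most of the information on a bend at these lengths.

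The third question was whether genes change the transcripts they use. Isoform usage was associated with length for 67 of 4348 genes with at least 2 measured transcripts (edgeR, gene-level F test of differential transcript usage, adjusted p under 0.05). Of these 67 genes, 32 were also associated with length in total expression. In simulated data this test exceeded its nominal error rate, with 16.8% of calls on unchanged genes at a usage change of 1 log2 per mm and 20.4% at 0.5. The 5 genes with the smallest p were LOC105250126, LOC105253785, LOC105252617, LOC105253655 and LOC105256214. In LOC105253655 the transcript XM_025408415.1 took 8.41% ± 4.93 of the gene's reads in the 16 shortest larvae and 50.9% ± 19.3 in the 16 longest (SD, n = 16 each; adjusted p = 8.76e-09). In LOC105256214 the transcript XM_011265947.3 went from 36.6% ± 5.64 to 60.1% ± 8.59 (adjusted p = 8.76e-09). In LOC105253785, with 18 annotated transcripts, XM_025414016.1 went from 32.4% ± 9.07 to 46.3% ± 9.31 (adjusted p = 1.66e-15). In LOC105252617 the minor transcript XM_025408000.1 went from 2.97% ± 0.920 to 1.16% ± 0.529 (adjusted p = 5.20e-09). In LOC105250126 the minor transcript XM_020027201.2 took 1.28% ± 1.26 in the 16 shortest larvae and was estimated at 0 in all of the 16 longest (adjusted p = 3.35e-18). The set of genes also depended on the libraries. Without the 15 libraries with high first-component scores 88 genes were called, 41 of them among the 67, and with these libraries as a covariate 99 were called, 46 of them among the 67. Limma on logit shares called 125 genes, 46 of them among the 67. A Simes test over transcripts called 16 genes and no longer called LOC105252617 or LOC105256214. With only transcripts holding at least 10% of their gene, LOC105250126 and LOC105252617 were no longer called.

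**Figure D5:**
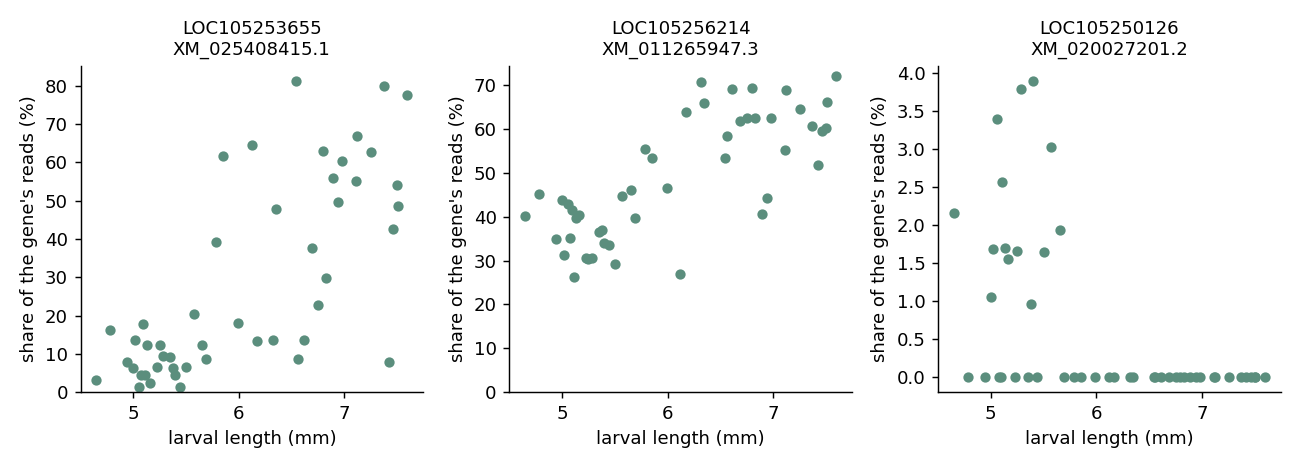
Share of the reads of 3 genes taken by 1 transcript in each of the 48 larvae (percent), against larval length in mm. XM_025408415.1 and XM_011265947.3 take larger shares in longer larvae, and XM_020027201.2 has reads in 14 larvae, all of 5653.55 µm or shorter.

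Co-expression was compared between the 24 smaller and the 24 larger larvae, since the study's title speaks of a rewired transcriptome. Among the 1000 genes of highest mean expression, after a line in length was removed, the mean absolute correlation between genes was 0.436 in the smaller and 0.452 in the larger larvae. The difference of 0.0159 was within the spread of 100 random splits of the larvae (-0.0968 to 0.0655, two-sided permutation p = 0.663). Of the 15 libraries with high first-component scores, only those of larvae No. 9, 15 and 17 were in the smaller set, so the sets also differ in this. The sign of the difference depended on the processing. With 2 principal components removed it was -0.0397 (permutation p = 0.0198), and without the 15 libraries with high first-component scores it was -0.0406 (permutation p = 0.0396), while p ran from 0.0198 to 0.950 over all alternatives.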

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

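The transcript that names no gene had reads in data that no comparison used. Its estimated reads exceeded the 3 reads that a count of 0 allows in all 48 libraries, ranging from 4 to 447 with a median of 72. In the 15 libraries with high first-component scores its reads ran from 63 to 447, and in the other 33 from 4 to 109. These reads are not scaled for depth, and the lowest counts, 4 and 8, are those of the shallow libraries of larvae No. 43 and No. 42. As a share of a library it took 0.000146% to 0.00124% in the 15 and 6.05e-05% to 0.000264% in the other 33. No explanation was tested for it, and its share of a library was at most 0.00124%.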

How the results depend on the processing

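Fits without larvae No. 42 and No. 43, without or adjusted for the 15 libraries with high first-component scores, or adjusted for each library's trend with transcript length, and the gene classes, were chosen only after the data were seen. Under all alternatives fitted to genes the number of rising genes lay between 1419 and 2657, and that of falling genes between 1136 and 2334. All of these counts lay within 1.5 times the reported 1769 and 1465, except 2657 rising genes for the 24 larger against the 24 smaller larvae, 2334 falling genes with 2 surrogate variables, and 2214 falling genes with the transcript-length trend as a covariate. Fits to single transcripts gave 1412 rising and 1277 falling of 19714 transcripts, and the authors' normalized table gave 1422 and 1682 of 19713 transcripts, which are not counts of genes. Leaving out 1 larva at a time gave 1613 to 1951 rising and 1340 to 1615 falling genes. Without the shallow libraries of larvae No. 42 and No. 43, 1653 genes rose and 1269 fell, with 2759 of the 3234 calls kept.

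The number of curved genes fell from 5735 to 170 with a quadratic term, which cannot follow every shape of the spline. It was 0 without the 15 libraries and 0 with these as a covariate, fits that leave little information on a bend because the 15 include 12 of the 14 larvae from 5850.88 to 6892.55 µm. The slope of LOC105257682 was -0.17 without the 15 libraries (edgeR adjusted p = 0.00315), against 0.39 with all larvae (adjusted p = 0.151), and its adjusted p ran from 0.00315 to 0.995 over the alternatives. For isoform usage, the Simes test called 16 genes and limma on logit shares 125, against 67. The alternatives planned for the 28 gene lists were not run on the lists but on the annotation classes. Fry called 1 gene class, misc_RNA, and gave pseudogenes an unadjusted p of 0.0471 (adjusted p = 0.118). Camera called 0 classes in the other settings. With the preset correlation it had 2 classes at an unadjusted p under 0.05, and in its remaining settings 0. The co-expression difference of 0.0159 changed sign in 3 settings, to -0.0028 for the 16 longest against the 16 shortest larvae (permutation p = 0.950), to -0.0397 with 2 components removed and to -0.0406 without the 15 libraries. Apart from the removal of libraries or of components, the cause of these changes was not tested. No paired analysis was possible because every larva is a separate animal in 1 group. For these counts, depth was examined only by leaving out larvae No. 42 and No. 43 and by a covariate for the total count, with which 1493 genes rose and 1136 fell.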

Other observations

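The tests of the 15 libraries with high first-component scores, the fit of curved genes with these as a covariate, the counts of runs of neighbouring genes, the values of the 3 adjacent abundant genes and the on-off transcript were chosen only after the results were seen, whereas the tests of permuted lengths and of neighbouring slopes were written before theirs.

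LOC105258900, LOC105258901 and LOC105258932 varied together over a range of 11261-fold in their joint TMM-scaled CPM. Within the 33 libraries with low first-component scores, log2 CPM of LOC105258900 and LOC105258901 had Pearson r = 0.999 and Spearman rho = 0.992, and within the other 15 libraries r = 0.999 and rho = 0.996. The permutation p was 1e-05 for all 6 relations among the 3 genes, the smallest it can give, with adjusted p = 1e-05. Without the 2 libraries farthest from the median, r for this pair was 0.997 and 0.999. How far reads are shared between these genes was not tested.

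Transcript XM_020027201.2 of LOC105250126 had estimated reads in 14 larvae and 0 in the other 34. All 14 were among the 21 shortest larvae, where its reads ran from 228 to 926, and the 27 larvae longer than 5653.55 µm had none. It took at most 3.90% of the gene's reads in a larva. Total expression of LOC105250126 did not pass the test for length (slope 0.07 ± 0.06 log2 per mm, edgeR adjusted p = 0.389) but passed in 4 of 14 alternative fits, with adjusted p from 0.000869 to 0.952.

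Genes that changed with length also lay in runs along the gene table. The table names no chromosome for any gene, so adjacent means next in its order, and a fall in the start position was taken as the start of a new sequence, which gave 478 sequences. There were 34 runs of at least 4 adjacent genes that changed in the same direction, 25 rising and 9 falling, against a median of 7 and at most 17 in 1000 shuffles. The longest run held 8 rising genes from LOC112638617 to LOC105256932, with a median slope of 0.52 log2 per mm, but runs of up to 9 genes occurred in the shuffles. LOC105249411, 1 of the 8 leading falling genes, lay in a run of 5 falling genes from LOC105249413 to LOC105249408.

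The slopes of neighbouring genes were alike over the whole table. For 8027 pairs of adjacent genes that do not overlap, the Spearman correlation of slopes across pairs was 0.149, against -0.0361 to 0.0329 in 1000 shuffles of gene order. Genes are not independent replicates, and adjacency and overlap rest on the sequences inferred from the order of the gene table. Reads shared between overlapping genes are argued against as the whole source, because the value of 0.149 comes from pairs without overlap, and genomic neighbourhood remains a candidate explanation. Tandem copies that share reads stay open, as no sequences were compared.

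On the first component 15 libraries stood apart from the other 33. A trend with transcript length is argued against as the whole cause, because 92.2% of the variance along this component was kept after the trend was removed from each library. Library depth is argued against as well, because 82.2% was kept after thinning all libraries to the lowest total. A spline of length explained 48.1% of the variance of the scores. Its bootstrap interval of 23.3% to 73.1% holds the bound of 50%, so the size of the part tied to length stays open. Length alone, as a smooth relation, is argued against, because larvae of similar length had scores on both sides of the gap. Larvae No. 15, 22, 9 and 23, from 4648.07 to 4997.25 µm, scored 33.8, -26.6, 38.3 and -47.8. Larvae No. 76, 68 and 26, from 7422.84 to 7503.35 µm, scored -19.9, 34.5 and -11.5. A difference in developmental timing between larvae of similar length, or a batch that follows the larva numbers, may play a part, but no label records either and neither was tested.

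With those libraries as a covariate the count of curved genes was 0 against 5735. This decides nothing between a curve with length and those libraries, because the 15 were chosen by expression and include 12 of the 14 larvae from 5850.88 to 6892.55 µm, so the covariate takes up a true curve as well. Of 100 orders of length only the real one gave as many curved genes, and the highest other order gave 873. A share of 1 in 100 is the smallest these orders can give, so chance is argued against for the count but not excluded. A relation with length and another difference between those larvae cannot be told apart here, and the 48.1% explained by length leaves both open.

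For genes associated with length, 2 of 100 orders, the real one included, gave as many as 3234 genes. This share is under 0.05, but the highest other order gave 3451, so the count alone does not exclude chance. Of the other orders 30 gave at least 1 gene, and 1 of them gave more genes than the real order, which points to a structure of the samples. With the 15 libraries as a covariate 3508 genes were called, and 2800 of the 3234 were kept. Without them 3524 were called, and 2547 were kept. These values argue against the split into 15 and 33 libraries as the whole source of the count. Any other structure of the samples stays open. For isoform usage, 4 of 100 orders gave as many as 67 genes, and the highest other order gave 198. This share is also under 0.05, but an order with several times the real count points to a structure of the samples. Without the 15 libraries 41 of the 67 genes were called again, and with these as a covariate 46, which does not settle the source of the others. Of the other orders 76 gave at least 1 gene, with a median of 2 genes, so permuted lengths also gave calls in the real data. Whether the high error rate of this test or a structure of the samples gave these calls stays open.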
